A study of Homo sapiens with 4 samples.

How the data were processed

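Fra-1 ChIP, DDX5 ChIP, IgG control ChIP and input DNA were each sequenced as 1 library from untreated BT549 cells, per the labels. The submitters' processing notes name CASAVA 1.8, the aligner Bowtie 0.12.9, HOMER (no version) and the genome build hg19, without saying which step each served. The peak caller and its settings are not given in the sources used here. The columns and arithmetic of the 4 deposited peak lists are those of a MACS2 peak table. Each list compares 1 ChIP library with 1 control library, and nothing was pooled.

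Per the file headers, the deposited signal of each peak is a pileup, the depth of ChIP fragments at the summit. Its values are whole numbers in the lists called against input. In those called against IgG they are multiples of 0.884 (Fra-1) and 0.998 (DDX5), to within a tolerance of 0.02 for 100% of the values examined, so the authors' ChIP signal was scaled down to the IgG library there. The deposited fold enrichment, per the file headers, is a ratio, and its values fit the pileup plus 1 over the local control level plus 1. The authors' table also holds −log10 values in 2 columns whose header cells are spreadsheet errors. The first equals the −log10 p-value of a Poisson upper tail of the pileup given that control level, with a median difference of 6.22e-06 in the Fra-1 list over input. The second was taken as the −log10 q-value, since it lies below the first and the largest q in the 4 lists is 0.0495. The fold, −log10 q and pileup were used only to describe, rank and filter peaks within a list.

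The control level at a peak was computed as the pileup plus 1 divided by the fold, minus 1. It cannot fall below the background that the caller assumed for the whole genome, so low control levels are censored at that background. In lists over input it is an input level and in lists over IgG an IgG level, in fragments at the depth of that list. Absolute read depths are unknown, so the depth limits on single peaks were not computed. Lists of different lengths partly reflect depth and threshold: a stronger antibody, a deeper library or a control with less background each lengthen a list.

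Peaks of different lists were compared by position, with an overlap of at least 1 bp as the main rule. Shares have 95% exact binomial (Clopper-Pearson) intervals, which cover counting error only, since neighbouring peaks are not independent and there is 1 library per antibody. For the same reason no p-value is given. Bootstrap intervals of differences between medians come from 1000 resamples of single peaks and have the same limit. Overlap of the lists was compared with 1000 shifts of the DDX5 list, circular within each chromosome (chromosomes 1 to 22 and X), by 1 to 10 Mb. The length of a chromosome was taken as the last peak end on it in any list. Deciles and quintiles are equal groups of peaks ranked by fold, IgG level or width. Quintiles of input level were cut by value with ties kept together, so they differ in size. The overlap and shift code was tested on simulated data, with fewer shifts. With 10762 simulated DDX5 peaks placed at uniformly random positions, independently of Fra-1, the ratio to shifts was 0.947. With 40% planted overlap, 40.6% was recovered. The real peaks gather in groups, so this checks the code and does not calibrate the ratio for the real lists. The code was run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

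The peak counts per list, the shares called again over IgG, the overlap of the antibodies, its ratio to shifted positions, their alternatives and the rule for naming peaks were fixed before the data were examined, except where the closing section says otherwise. The split of Fra-1 peaks by calling over IgG, the deciles and quintiles, the widths and folds of common and single peaks, the summit distances, the comparison of Fra-1 over IgG with DDX5 over input against shifts and the spread over chromosomes were chosen after the data were seen. The rule took, on chromosomes 1 to 22 and X, the 5 peaks with the highest score in each list, the 5 common sites with the lowest sum of ranks in both lists over input, and the 5 highest Fra-1-only and DDX5-only peaks. It had assumed a HOMER score, which these lists do not carry, and the −log10 q was used in its place, with ties ordered by pileup. The same replacement was made in the alternative that keeps peaks at or above the median score. The 7 peaks on chromosome 14 were singled out as a group after their values were seen. Alternatives were stricter peak thresholds (at least 8-fold, or −log10 q at or above the list's median), other rules for overlap (centres within 100 bp or 500 bp, at least 50% of either peak), the other control, shorter shifts of 5 to 50 kb, and chromosomes 1 to 22 and X only.

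Planned analyses that need an hg19 annotation or sequence were not run. These were the shares of peaks at promoters and with an AP-1 motif, the overlap within classes of distance to transcription start sites, gene lists with nearby peaks, the nearest gene of named peaks and the loci of the genes encoding Fra-1 and DDX5. The reference table used here has the coordinates of another build and was not set against these positions.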

Results

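Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Fra-1 and DDX5 on the genome of BT549 cells, a human breast cancer cell line that lacks oestrogen receptor alpha. Fra-1 is a Fos-family subunit of the AP-1 transcription factor, which binds DNA directly. DDX5 is a DEAD-box RNA helicase that also acts as a transcriptional coactivator. The cells were untreated. The 4 libraries were 1 Fra-1 ChIP, 1 DDX5 ChIP, 1 ChIP with normal rabbit IgG and 1 of input DNA, that is, sonicated chromatin without immunoprecipitation. Both controls measure background: input DNA records copy number and how readily a region is recovered and aligned, and the IgG library records in addition what is pulled down without a specific antibody. The authors called the peaks of each antibody separately against input and against IgG, which gave 4 lists. With 1 library per antibody there are no replicates, so no difference between the antibodies could be tested, and the 95% exact binomial intervals given for shares cover counting error only. The fold enrichment and the pileup (the depth of ChIP fragments at the summit) of each peak are the authors' values. Absolute sequencing depths are not given in the sources used here. The scaling of the pileups puts the depth of the IgG library at 0.884 times that of the Fra-1 library and 0.998 times that of the DDX5 library. Positions are in hg19. Genes and motifs at the peaks were not analysed here, so peaks are named by position.

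Fra-1 was enriched at many sites. Over input 30571 peaks were listed, with a median width of 317 bp and a median fold of 5.37 (interquartile range 3.99 to 9.03). Of these, 9028 (29.5%) reached 8-fold. Over IgG 16133 peaks were listed, with a median fold of 6.82, and 6254 (38.8%) reached 8-fold. The Fra-1 peak over input with the highest −log10 q lay at chromosome 1, 115721762 to 115722775, with a pileup of 288 and a fold of 49.0. The next 4 were at chromosome 20, 33893240 to 33894368 (36.3-fold), chromosome 8, 49502540 to 49503270 (38.8-fold), chromosome 20, 11242003 to 11242803 (44.2-fold), and chromosome 6, 169470552 to 169471398 (42.9-fold). All 5 were also in the IgG-called list, at 8.96-fold to 17.6-fold, and all 5 overlapped a DDX5 peak called over input, at 3.72-fold to 7.89-fold. The 5 leading Fra-1 peaks over IgG were at chromosome 6, 4358777 to 4359427 (33.8-fold), chromosome 8, 126231477 to 126231894 (33.8-fold), chromosome 13, 49323754 to 49324553 (27.4-fold), chromosome 6, 122115753 to 122116166 (37.2-fold), and chromosome 5, 77175494 to 77176223 (26.5-fold). Of these, the peak at 4358777 on chromosome 6 and that on chromosome 5 overlapped a DDX5 peak, and the other 3 overlapped none.

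DDX5 enrichment was weaker, and it depended on the control. Over input 10836 peaks were listed, with a median width of 285 bp and a median fold of 4.16 (3.61 to 4.89). Of these, 247 (2.28%) reached 8-fold. Over IgG the list held 61 peaks, 3 of which reached 8-fold. The 5 leading DDX5 peaks over input included 4 within a short stretch of chromosome 17. They lay at 18966529 to 18967581 (38.1-fold), 19015059 to 19016010 (27.1-fold), 19091200 to 19092268 (32.1-fold) and 18965093 to 18966111 (26.8-fold). The other was at chromosome 22, 43011166 to 43011848 (29.1-fold). All 5 overlapped a Fra-1 peak over input, at 16.7-fold to 27.3-fold, and none overlapped a Fra-1 peak over IgG. Against IgG, DDX5 peaks were listed at 2 of the 5, at 19015059 on chromosome 17 (1.62-fold) and on chromosome 22 (2.05-fold). The input level at these 5 leading peaks was 4.29 to 7.04, against a median of 3.83 in the DDX5 list over input. Whether these stretches hold sequence present in many copies, such as genes of small or ribosomal RNAs, was not analysed here, and it bears on what these folds mean.

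The 2 controls kept very different shares of each list. Of the 30571 Fra-1 peaks over input, 15443 (50.5%, interval 49.95% to 51.1%) overlapped a Fra-1 peak over IgG. At 8-fold or more over input the share was 97.6%. Fra-1 peaks called again over IgG had a median fold of 8.88 over input, and those not called again 4.11. Of the 10836 DDX5 peaks over input, 55 (0.508%, 0.383% to 0.660%) overlapped a DDX5 peak over IgG, and of the 247 peaks of at least 8-fold, 32 (13.0%) did. In the other direction, 15759 of 16133 Fra-1 peaks over IgG (97.7%) and 60 of 61 DDX5 peaks over IgG overlapped a peak of the same antibody over input.

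The series set out to find binding events that are specific to Fra-1 or DDX5 and events common to both. In the lists called over input, 6700 of 10836 DDX5 peaks (61.8%, 60.9% to 62.7%) overlapped a Fra-1 peak by at least 1 bp, and 6650 of 30571 Fra-1 peaks (21.8%, 21.3% to 22.2%) overlapped a DDX5 peak. This left 23921 Fra-1-only and 4136 DDX5-only peaks. The summits of common peaks lay a median of 72 bp apart (29 to 166 bp), and 60.6% were within 100 bp. These pairs were chosen for overlapping, with the nearest summit taken, and no distance under shifts was computed, so the closeness is only descriptive. On chromosomes 1 to 22 and X, 6655 DDX5 peaks overlapped a Fra-1 peak, against a mean of 105.6 (range 74 to 141) when the DDX5 list was shifted by 1 to 10 Mb along each chromosome 1000 times, a ratio of 63.0. With shifts of 5 to 50 kb, which keep peaks within their neighbourhood, the ratio was 20.3. Both lists were called against the same input library, so the chance values of that library enter both. With the lists called over IgG, 8 of 61 DDX5 peaks (13.1%, 5.84% to 24.2%) and 8 of 16133 Fra-1 peaks (0.0496%) overlapped the other antibody. The mean number under shifts was 0.257, a ratio of 31.1.

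DDX5 peaks with the highest folds over input overlapped Fra-1 peaks over input more often. In deciles of DDX5 fold over input, the share with a Fra-1 peak was 49.0% to 57.0% in the lower 6 deciles and rose to 90.7% (88.8% to 92.3%) in the highest. Of the 1084 peaks in that decile, 46 were also called over IgG. DDX5 peaks with Fra-1 overlap were also wider than those without (medians 324 and 246 bp), with a higher median input level (4.29 and 3.43). Common Fra-1 peaks were wider than Fra-1-only peaks, with medians of 410.5 and 301 bp, and had a lower median fold, 4.75 against 5.64. Within the peaks called again over IgG the median fold was higher with DDX5 overlap than without, 15.2 against 8.49, as it was within those not called again, 4.37 against 3.98. The 5 common sites with the best ranks in both lists were at chromosome 20, 62330022 to 62331564 (Fra-1 28.1-fold, DDX5 8.25-fold over input), chromosome 20, 11242003 to 11242803 (44.2-fold and 7.89-fold), chromosome 17, 18966489 to 18967538 (27.3-fold and 38.1-fold), chromosome 15, 102501526 to 102502174 (27.1-fold and 5.67-fold), and chromosome 11, 65686254 to 65687057 (49.7-fold and 8.12-fold). At the first of these sites the DDX5 peak over input spanned 62327472 to 62331614, and its summit, at 62328139, lay outside the Fra-1 peak. The 8.25-fold thus belongs to a position beside that Fra-1 peak. Over IgG, Fra-1 peaks were listed at 4 of these sites, all but the one on chromosome 17, and a DDX5 peak was listed only at 62330022 on chromosome 20 (2.48-fold).

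The overlap with DDX5 differed between Fra-1 peaks that were and were not called over IgG, a split made after the data were seen. Of the 15443 Fra-1 peaks over input that were called again over IgG, 1448 (9.38%, 8.92% to 9.85%) overlapped a DDX5 peak. Of the 15128 that were not, 5202 (34.4%, 33.6% to 35.1%) did, and these made up 78.2% of the common Fra-1 peaks. In the Fra-1 list over IgG, the share with DDX5 overlap went from 0.868% (0.577% to 1.25%) in the quintile of peaks with the lowest IgG level, median 2.80, to 28.1% (26.5% to 29.7%) in the quintile with the highest, median 11.0. Among peaks called with both controls, the share went from 3.17% (2.36% to 4.17%) in the lowest decile of Fra-1 fold over input to 31.9% (29.6% to 34.3%) in the highest, while the median IgG level went from 4.20 to 8.0. Among peaks not called over IgG, the share was 31.4% in the lowest decile of fold over input, 26.7% in decile 2 and 58.2% in the highest. In deciles of fold over IgG, the share in the Fra-1 list over IgG was 15.2% (13.5% to 17.0%) in the lowest, 5.08% (4.06% to 6.27%) in decile 3 and 12.2% (10.6% to 13.9%) in the highest. In deciles of fold over input, the share of all Fra-1 peaks over input was 27.2% in the lowest, 10.9% in decile 8 and 23.9% in the highest. Against the Fra-1 list over IgG, 1424 DDX5 peaks over input on chromosomes 1 to 22 and X overlapped, against a mean of 44.2 under shifts, a ratio of 32.2. These lists were called against different controls.

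**Figure D1:**
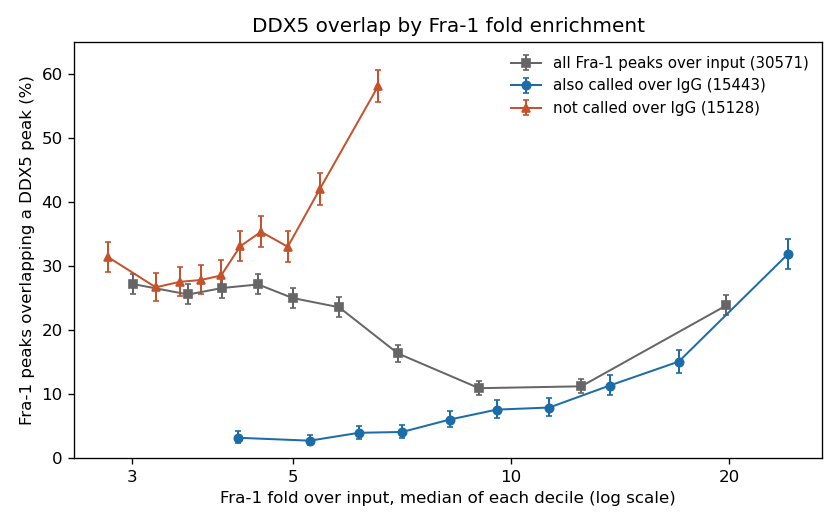
Share of Fra-1 peaks over input that overlap a DDX5 peak over input (percent, y axis) against the median Fra-1 fold over input of each decile (log scale, x axis), for all peaks, those also called over IgG and those not called over IgG. Points are deciles and bars are 95% exact binomial intervals, which cover counting error only. Among peaks also called over IgG the share goes from 3.17% to 31.9%, in the highest decile of those not called it is 58.2%, and among all peaks it goes from 27.2% to 10.9% in decile 8 and 23.9% in the highest.

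**Figure D2:**
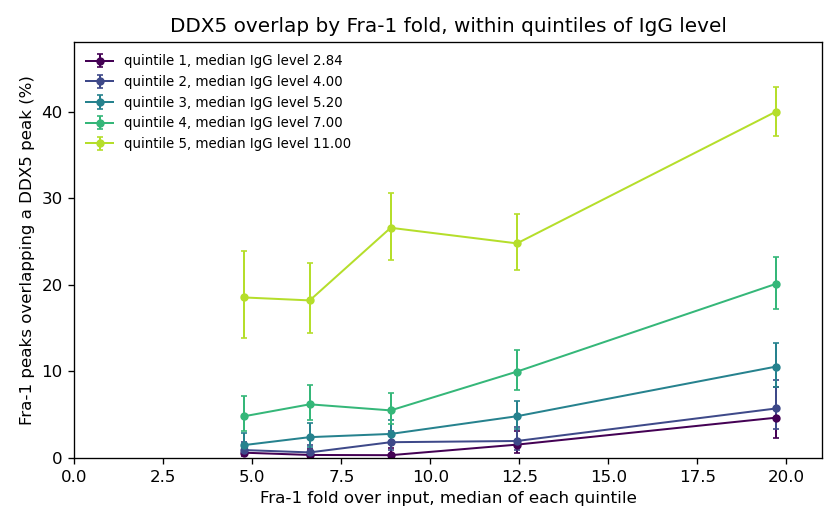
Share of Fra-1 peaks called with both controls that overlap a DDX5 peak over input (percent, y axis) against the median Fra-1 fold over input of each quintile (x axis), with 1 line for each quintile of the IgG level at the peak. Bars are 95% exact binomial intervals. The highest quintile of fold lies above the lowest on every line, at 4.66% against 0.622% for the lowest IgG level and 40.0% against 18.5% for the highest.

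Sites listed for Fra-1 alone were also strong. The 5 leading Fra-1-only peaks over input lay at chromosome 8, 132868794 to 132869807 (28.2-fold), chromosome 13, 49323747 to 49324542 (42.5-fold), chromosome 20, 56273286 to 56273976 (31.3-fold), chromosome 6, 56803317 to 56803981 (38.7-fold), and chromosome 10, 79110350 to 79110825 (30.8-fold). All 5 were called over IgG, at 13.3-fold to 27.4-fold. The DDX5-only peaks had a median fold of 3.97 over input, against 4.35 for DDX5 peaks that overlapped Fra-1.

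The leading DDX5-only sites lay together on chromosome 14. Of the 5 with the highest −log10 q, 4 were at 64727021 to 64727606 (25.8-fold over input), 64749226 to 64749783 (21.2-fold), 64701577 to 64702007 (13.0-fold) and 64723817 to 64724220 (11.1-fold), and the other was at X, 3733555 to 3733966 (8.97-fold). The 4 on chromosome 14 were also called over IgG and the one on X was not. In the DDX5 list over IgG, the leading 5 peaks were at chromosome 14, 64727036 to 64727571 (15.8-fold over IgG), 64749254 to 64749764 (11.1-fold), 64746618 to 64746969 (10.2-fold) and 64701639 to 64701962 (5.99-fold), and at chromosome 1, 149824189 to 149824503 (3.70-fold). The stretch of 48.1 kb from 64701639 to 64749764 on chromosome 14 held 7 of the 61 peaks, which had the 7 highest folds of the list, 5.59 to 15.8 over IgG. No Fra-1 peak overlapped any of the 7, and the IgG level at them was 2.67 to 7.0. The other 54 DDX5 peaks over IgG had a median fold of 2.89 and lay where the IgG level was high, with a median of 17.0 against a lowest level of 2.67 in the list. Of these 54, 47 overlapped a Fra-1 peak over input and 8 a Fra-1 peak over IgG.

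**Figure D3:**
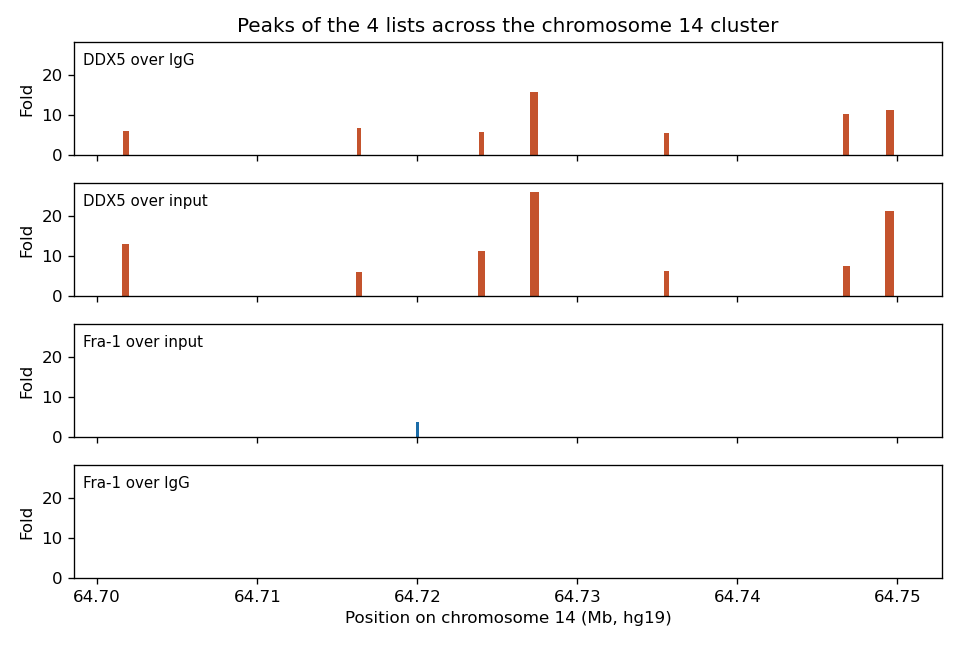
Map of chromosome 14 (hg19, Mb, x axis) around 64701639 to 64749764, with a panel for each of the 4 lists. Each bar spans a peak and its height is the peak's fold over the control named in the panel. Both DDX5 lists have 7 peaks here, at up to 15.8-fold over IgG and 25.8-fold over input, the Fra-1 list over input has 1 at 3.73-fold and the Fra-1 list over IgG has none.

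The lists also differed in how they spread over the chromosomes. Chromosome 19 held 861 of 10762 DDX5 peaks over input (8.0%, 7.49% to 8.53%), 3.59% (3.39% to 3.81%) of Fra-1 peaks over input and 1.78% (1.58% to 1.99%) of Fra-1 peaks over IgG. It held 10.0% of the DDX5-only peaks and 7.12% of the common Fra-1 peaks. Chromosome 17 held 7.18% of DDX5 peaks, 4.48% of Fra-1 peaks over input and 3.17% of those over IgG. The order was the opposite on chromosome 4, with 1.85%, 4.13% and 5.52%, on chromosome 2, with 3.33%, 6.0% and 7.42%, and on chromosome 18, with 0.808%, 1.75% and 2.22%. For these 5 chromosomes the intervals of the 3 lists did not overlap. On chromosomes 19 and 4, the Fra-1 peaks not called over IgG lay between DDX5 and Fra-1 over input, with 5.46% and 2.65%.

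**Figure D4:**
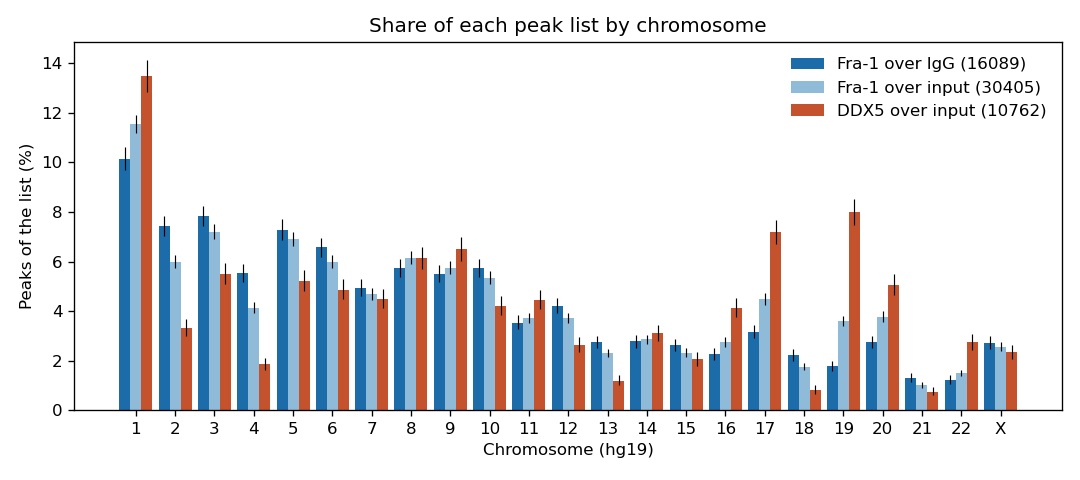
Share of the peaks of each list (percent, y axis) on chromosomes 1 to 22 and X (x axis), for Fra-1 over IgG, Fra-1 over input and DDX5 over input. Bars start at 0 and the lines on them are 95% exact binomial intervals. DDX5 has the highest share of the 3 lists on chromosome 19 (8.0%) and the lowest on chromosome 4 (1.85%).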

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

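The −log10 q threshold was planned as a HOMER score; the counts at 8-fold, and the split of Fra-1 peaks by IgG calling with its alternatives, were chosen after the data were seen. Of 34 alternatives, 3 stayed within the interval of the reported value or, for peak counts, which have no interval, within 1.5 times of it. These were both overlap shares on chromosomes 1 to 22 and X (61.8% and 21.7%) and the ratio to shifted positions above the median −log10 q (63.7). The share of DDX5 peaks with a Fra-1 peak, 61.8%, became 36.3% with centres within 100 bp, 57.7% with at least 50% of either peak, 64.8% with centres within 500 bp, 13.1% with the IgG lists, 13.2% with Fra-1 over IgG and DDX5 over input, 45.3% with both lists at 8-fold and 35.4% with both above their median. The share of Fra-1 peaks with a DDX5 peak, 21.8%, became 12.9%, 20.3%, 22.9%, 0.0496%, 8.68%, 1.28% and 12.2% in the same order. Shifts of 5 to 50 kb gave a ratio of 20.3, the IgG lists 31.1 and 8-fold peaks 98.5, against 63.0. The share of Fra-1 peaks called again over IgG, 50.5%, became 46.8% with centres within 100 bp, 97.6% and 86.3% with only the list over input at 8-fold and above its median. That of DDX5, 0.508%, became 0.305%, 13.0% and 0.997%. DDX5 overlap of Fra-1 peaks called over IgG, 9.38%, became 5.19% (centres) and 5.60% (both antibodies' lists over input above their median), and of those not called, 34.4%, became 20.7% and 53.5%, so the latter was higher each time. At 8-fold the lists held 9028 and 6254 Fra-1 and 247 and 3 DDX5 peaks (over input and IgG). Stricter overlap rules lower a share, and thresholds lower a count, by construction; thresholds on both lists also remove partners. For every other move, the shares and ratios that rose under thresholds included, the cause was not tested. The shares that rest on 247 or 61 DDX5 peaks have the wide intervals of such counts. The promoter, AP-1 motif, gene-list and distance-matched alternatives were not run.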

Other observations

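All tests in this part were chosen after the patterns were seen; for shifted peaks in the highest decile of fold, the input level over deciles of fold and the shares within quintiles of input level, the bound was set before the test's own result was seen. Peaks of both antibodies over input gathered in some of the same stretches. When peaks at most 12.5 kb apart were joined on chromosomes 1 to 22 and X, the Fra-1 list over input formed 18162 groups, of which 658 held 5 or more peaks, and the DDX5 list over input formed 6761 groups, of which 260 did. The fullest DDX5 group held 41 peaks within 38.5 kb at chromosome 1, 228744226 to 228782717, with a median fold of 3.11, and 36 of these overlapped a Fra-1 peak over input. The fullest Fra-1 group over input, 35 peaks with a median fold of 3.13, lay in the same stretch at 228744291 to 228782197. The Fra-1 list over IgG formed 10576 groups, of which 189 held 5 or more, and its fullest held 10 peaks, for example within 26.1 kb at chromosome 1, 223888654 to 223914762. The next DDX5 groups were 39 peaks at chromosome 19, 1085771 to 1208123, and 38 at chromosome 22, 46449744 to 46512669, of which 15 and 15 overlapped Fra-1. Both lists over input also held 35 peaks on one unplaced scaffold, covering 34.5 kb for Fra-1 and 41.6 kb for DDX5 at median folds of 1.47 and 1.47, and neither list over IgG held any there. Whether these stretches and the scaffold hold sequence present in many copies, such as genes of small or ribosomal RNAs, was not analysed here, and their counts and folds do not separate that from binding.

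Most of the overlap between the antibodies lay at Fra-1 peaks that were not called over IgG (34.4% against 9.38% with DDX5 overlap). Low coverage of the shared input library would raise the fold of both antibodies, and the peaks not called did have a lower median input level, 4.26 against 4.84. Fra-1 peaks with DDX5 overlap, by contrast, had a higher median input level than those without, 4.84 against 4.38 (bootstrap interval of the difference 0.387 to 0.581). Within each of 5 quintiles of input level, however, the share with DDX5 overlap was at least 3.28 times as high among peaks not called as among those called, with intervals apart, which argues against low input as the whole cause. Enrichment that the IgG library shares, such as at readily recovered chromatin, remains a candidate explanation: within the Fra-1 list over IgG the share with DDX5 overlap was 32.4 times as high in the highest quintile of IgG level as in the lowest. DDX5 present at the same active regions would give the same relation, and no test here separates these. The median Fra-1 pileup rose too over these quintiles, from 28.3 to 74.3, and the median width from 271 to 377 bp. The ratio is thus not of IgG level alone. Among peaks called with both controls, in the lowest quintile of fold over input, the share still went from 0.622% to 18.5% over quintiles of IgG level. Neither comparison covers the peaks not called over IgG.

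Among Fra-1 peaks called with both controls, DDX5 overlap rose 10.1 times from the lowest to the highest decile of Fra-1 fold over input. It rose among peaks not called over IgG as well (31.4% in the lowest, 26.7% in decile 2, 58.2% in the highest). It showed no net rise by fold over IgG (15.2%, 5.08% in decile 3, 12.2%) or over all Fra-1 peaks over input (27.2%, 10.9% in decile 8, 23.9%). Among the latter the share called over IgG went from 6.18% to 99.6%. Calling over IgG depends on both the Fra-1 signal and the IgG level, so the split itself can tie fold over input to IgG level in both groups. The IgG level at peaks not called is not known, so their rise could not be set against it and is not separate support. Among peaks called with both controls the IgG level rose too, but within each of 5 quintiles of IgG level the share was still at least 2.16 times as high in the highest quintile of fold as in the lowest, which argues against the IgG level as the whole cause. Chance overlap of wider peaks would give 0.387% in the highest decile, against 31.9% observed. The rise appeared in the 2 widest quintiles of peak width, however (8.0% to 18.5% and 21.1% to 37.4%). In the other 3 the intervals of the lowest and highest quintile of fold overlapped. The middle quintile of width, with 390 and 618 peaks in these, went from 3.33% to 5.50%. Width also went with overlap at low fold. In the lowest quintile of fold the share was 0.314% in the narrowest and 21.1% in the widest quintile of width. The narrowest quintile held only 3 peaks in the highest quintile of fold and the next held 143, so a rise among narrow peaks could not be judged well. The labels appear to give the same lane for all 4 libraries. Reads carried over from the Fra-1 library into every other library of the lane would raise the input level where Fra-1 signal is high. Over deciles of Fra-1 fold over IgG the median input level rose by 0 (bootstrap interval -0.194 to 0). Fold over IgG divides by the IgG level, however, whose median fell from 8.0 to 5.0 over such deciles of the Fra-1 list over IgG. The ranking thus favours low background, so the flat input level cannot decide on carryover. Carryover, into all the other libraries or into the DDX5 and IgG libraries alone, remains open, as does an effect of peak width. Binding of DDX5 together with Fra-1, the biological explanation that the design names, remains open too, and none of the tests here decides it.

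The 7 DDX5 peaks on chromosome 14 stand apart from the rest of the DDX5 list over IgG. More copies of the stretch in BT549 would raise the input there, but its median level at the 7 peaks was at most 0.700 times the median of the DDX5 list over input, an upper bound since 4 of the 7 lie at the lowest level the list can show. Enrichment that the IgG library shares is argued against as the whole cause at the 4 peaks that the DDX5-only ranking over input had named, by a fold over IgG of at least 5.84. The other peak of that ranking, on X, was not called over IgG. The stretch was singled out after its values were seen, so this covers the 4 peaks alone. At these 4 the IgG level was 5.0 to 7.0 while the input level was at its lowest, 2.68, so a partial share in the IgG library is not excluded. The other 3, at 5.59-fold or more, were picked from the list called over IgG, so their fold does not test that explanation. DNA from outside the cells' genome, such as a construct in the DDX5 library alone, could give separate peaks of this kind. The 0 Fra-1 peaks that overlap the 7 leave it open, as they do DDX5 binding without Fra-1. These cannot be told apart without an annotation of the build or the reads.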
